A study of Homo sapiens with 15 samples.

How the data were processed

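Poly-A RNA was measured by sequencing in 15 libraries of 2 human cell lines that carried KRAB-dCas9, a catalytically inactive Cas9 fused to a transcriptional repressor domain, together with a guide RNA. The 9 Jurkat libraries formed 3 groups, with 3 Safe Harbor control, 4 sg4 and 2 sg8 libraries. The 6 A375 libraries formed 3 groups of 2, titled Safe Harbor, 20nt and g[9]nt, the last of which is written g[9nt] here. The labels do not say which guide addresses which site in which line, nor whether replicates were separate cultures, so p-values measure only the spread between these samples.

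The deposited files hold estimated counts per transcript, made by the authors with kallisto 0.46.1 on build hg38, per the submitters' processing notes. The transcriptome release, the kallisto options and the strand setting are not given in the sources used here. The deposited lengths and effective lengths of the transcripts were used for 1 alternative and for an estimate of fragment length, taken from transcripts longer than 5000 bases. Each file listed 188753 transcripts, and between 43.41% and 57.5% of the values were not whole numbers. Total estimated counts per library ranged from 20.3 to 92.9 M.

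Transcripts were joined to genes through GENCODE 29 by identifier without version, which placed 89.93% of transcripts and between 97.13% and 97.39% of the counts of a library in 35544 genes. The identifier with its version matched for 84.1% of transcripts. The unmatched transcripts were left out, so genes whose newer transcripts are among them may be counted too low. Reads that neighbouring, readthrough or copied genes share are split by the estimate, so values of NOTCH1, CANX, PARN, DDX39B, readthrough genes and pseudogenes are uncertain. Estimated counts were summed per gene and rounded.

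Each cell line was fitted separately with edgeR 4.0.16, with trimmed-mean (TMM) normalization, the filterByExpr filter on low counts by group, and the quasi-likelihood F test. This left 16358 genes in A375 and 16108 in Jurkat, with 3 and 6 residual degrees of freedom. All groups of a line shared 1 estimate of spread, and the common biological coefficient of variation was 0.0733 in A375 and 0.213 in Jurkat. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and fold changes are on the log2 scale with their standard error (SE). Levels are counts scaled to library size (CPM), as mean and standard deviation (SD). Intervals and floors cover counting error only, at 95%, and the floor for a group at 0 is 3 counts over the group. The tests were two-sided.

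Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test was run with an estimated correlation, and fry was run beside it. The 39 lists cover the construct, the heterochromatin and KRAB pathway, CTCF and cohesin, clustered protocadherins, imprinted genes, HOX genes, the CD81 region, tetraspanins and CD81 partners. They also cover T cell receptor signalling, T cell activation, T-ALL regulators, the melanocyte lineage, dedifferentiated melanoma, MAPK output, p53, interferon, NF-kB, the unfolded protein response, ATF4, heat shock, cholesterol synthesis, hypoxia and glycolysis, MHC and apoptosis. The rest hold S phase, G2M phase, replication histones, ribosomal proteins, nucleolus and MYC, mitochondrial transcripts, extracellular matrix, and markers of B, myeloid, erythroid, NK, endothelial, epithelial and neural cells. The construct list was too small to test, so ZNF10 is given per library. The melanoma lists were set beforehand as a check for contamination in Jurkat, and the T cell lists as one in A375.

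The groups, the tests, the lists and the rule for named genes were chosen before the data were examined. The rule takes CD81 everywhere, CTCF in Jurkat, and in A375 the genes that start within 500 kb of CD81. It adds the 10 largest rises and the 10 largest falls with a mean log2 CPM of at least 1, groups that do not overlap and an approved-style symbol. Up to 4 members with the smallest p per called list and up to 3 of any other list described are also named, and with fewer than 5 such genes the 5 with the smallest p are named. Genes named outside this rule are said to have been chosen after their values were seen.

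Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, length-scaled counts, only the 2 groups compared, a replicate block, a minimum change of 2-fold, an estimated list correlation, and leaving out each library. Alternatives chosen after seeing the data were a term for library depth, only the shallow or only the deep Jurkat libraries, a minimum of 1 CPM in every group, and removal of a trend with transcript length. Libraries of sg4 and Safe Harbor that share a replicate number deviated from their group means together across genes, with correlations of 0.142, 0.423 and 0.529. The labels give only the numbers, and sg4 replicates 1 and 2 each correlated slightly more with another Safe Harbor library, at 0.152 and 0.464. The highest correlation, 0.643, joined sg4 replicate 4 and Safe Harbor replicate 3, which differ in number but are both deep. Pairs by replicate number are therefore not established by these data. Correlations between comparisons that share control libraries are given beside 20 simulations of unchanged groups.

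The fits were tested on simulated counts with known changes. The changed genes were drawn only from genes averaging at least 1 CPM. Counts were drawn independently per library, without the depth structure of the Jurkat libraries, so recovery in the real comparisons can differ. For 20nt against Safe Harbor, 54 of 62 genes changed 2-fold were recovered (87.1%), in a fit of 16112 genes. For g[9nt] it was 54 of 59 against Safe Harbor (91.5%, fit of 16126) and 62 of 65 against 20nt (95.4%, fit of 16132). The same share was 46 of 67 for sg4 against Safe Harbor (68.7%, fit of 15663 genes) and 34 of 65 for sg8 against Safe Harbor (52.3%, fit of 15662). For sg4 against sg8 it was 43 of 63 (68.3%, fit of 15677). False calls made up 9.5%, 11.3%, 7.29%, 7.25%, 6.31% and 5.38% of calls in the same order. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.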

Results

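Gene expression was measured by poly-A RNA sequencing in Jurkat, a T lymphoblast line, and A375, a melanoma line, each with a KRAB-dCas9 repressor and 1 of 3 kinds of guide. Jurkat carried a Safe Harbor control guide (n = 3), sg4 (n = 4) or sg8 (n = 2), and A375 carried a Safe Harbor control guide, a 20nt guide or the truncated g[9nt] guide (n = 2 each). Jurkat libraries held 34.9, 28.5 and 80.4 M estimated counts for Safe Harbor, 78.2, 20.3, 84.4 and 92.9 M for sg4, and 27.1 and 24.8 M for sg8. A375 libraries held 39.4 and 36.1 M for Safe Harbor, 42.8 and 35.6 M for 20nt, and 29.9 and 31.9 M for g[9nt]. ZNF10, the gene from which the KRAB domain of many dCas9 repressors is taken, was present in each library. Its level was 48.5 and 55.9 CPM in A375 Safe Harbor, 110 and 71.8 CPM in 20nt, and 43.1 and 68.1 CPM in g[9nt]. In Jurkat, ZNF10 measured 57.1, 58.8 and 42.2 CPM in Safe Harbor, 29.6, 44, 48.1 and 48.4 CPM in sg4, and 71.8 and 68.3 CPM in sg8.

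The series names the CD81 promoter and CTCF sites as targets. CD81 was examined first in each group, and CTCF in Jurkat. CTCF sites are bound by the CTCF protein, so the level of the CTCF transcript does not measure the effect of a guide at such a site. CD81 (ENSG00000110651, chromosome 11, 2376177 to 2397419, plus strand, hg38) encodes a tetraspanin of the cell surface. In A375 it fell from 103 ± 0.492 CPM (SD, n = 2) with Safe Harbor to 13.3 ± 0.888 CPM (SD, n = 2) with the 20nt guide, a 7.73-fold drop (edgeR log2 fold change -2.95, SE 0.14, adjusted p = 9.1e-05). With g[9nt] it fell to 21.6 ± 5.67 CPM (SD, n = 2), a 4.78-fold drop (edgeR log2 fold change -2.26, SE 0.14, adjusted p = 6.4e-05). The single libraries gave 103 and 103 CPM, 13.9 and 12.7 CPM, and 25.6 and 17.6 CPM. CD81 was 1.62-fold higher with g[9nt] than with the 20nt guide (edgeR log2 fold change 0.69, SE 0.15, adjusted p = 0.0282), a call that was lost with length-scaled counts, with only those 2 groups in the fit, and without any 1 library of Safe Harbor or 20nt. In Jurkat, CD81 stood at 161 ± 15.7 CPM (SD, n = 3) with Safe Harbor, 167 ± 32.6 CPM (SD, n = 4) with sg4 and 183 ± 8.45 CPM (SD, n = 2) with sg8, and neither difference passed (edgeR adjusted p = 1 and 0.925). CTCF, the insulator protein, stood at 279 ± 31.7, 272 ± 19.9 and 289 ± 17.8 CPM in the same Jurkat groups, and neither difference passed (edgeR adjusted p = 1 and 0.935).

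**Figure D1:**
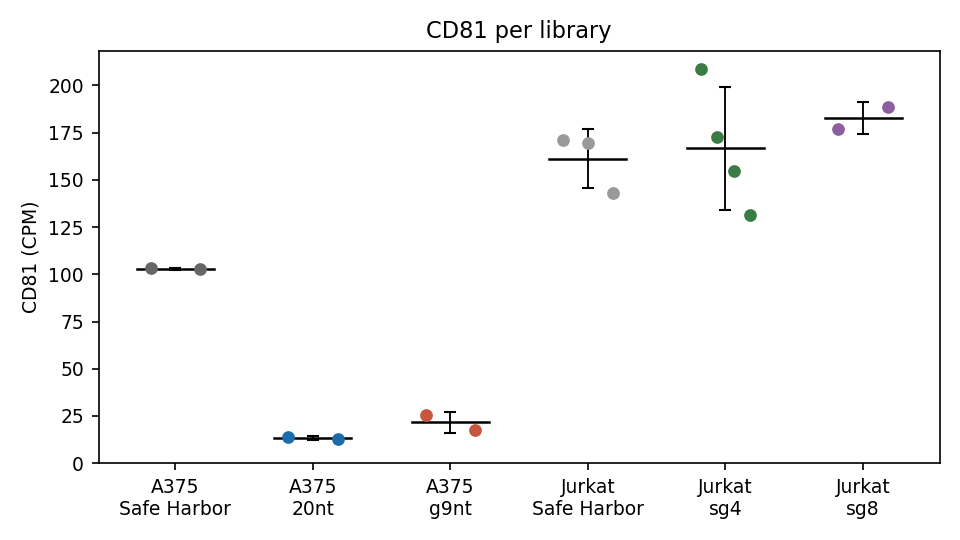
CD81 in CPM in each of the 15 libraries by group, with the group mean as a bar and the SD as an error bar. In A375 the 2 Safe Harbor libraries lie at 103 CPM, and the 20nt and g[9nt] libraries lie between 12.7 and 25.6 CPM.

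Of the 17 annotated genes that start within 500 kb of CD81, 5 were tested in A375, CD81 included. TSSC4 went from 34.4 CPM with Safe Harbor to 27.4 CPM with the 20nt guide (log2 fold change -0.33, edgeR adjusted p = 0.0835). MRPL23, a mitochondrial ribosomal protein, went from 38.3 to 31.2 CPM (log2 fold change -0.29, edgeR adjusted p = 0.111), and neither passed the test. Both were higher with g[9nt] than with 20nt, TSSC4 by 0.41 (edgeR adjusted p = 0.0313) and MRPL23 by 0.38 (edgeR adjusted p = 0.0418) on the log2 scale. TSPAN32 was near the detection limit and did not change. IGF2, an imprinted growth factor, was 24.2 CPM with Safe Harbor, 19.8 CPM with 20nt and 0.101 CPM with g[9nt], and fell in g[9nt] together with the liver-type transcripts described further on.

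To determine what else the 20nt guide altered in A375, its libraries were compared with Safe Harbor. Among the targets of ATF4, some rose: CHAC1, a glutathione-degrading enzyme, went from 3.10 ± 0.305 to 8.0 ± 0.968 CPM (log2 fold change 1.37, SE 0.17, n = 2 and 2, edgeR adjusted p = 0.0251). ASNS, the asparagine synthetase, rose by 0.60 and SLC7A11, the cystine transporter, by 0.57 on the log2 scale. The fibrillar collagens COL1A1 and COL1A2 rose by 0.79 and 0.80, and SNX25, a sorting nexin, went from 8.14 ± 0.278 to 22.9 ± 2.59 CPM (a 2.82-fold rise, log2 SE 0.21, edgeR adjusted p = 0.0294). The metallothionein MT2A fell from 94.6 ± 7.27 to 53.8 ± 1.18 CPM (log2 fold change -0.81, SE 0.13, edgeR adjusted p = 0.0359). NTHL1, a DNA glycosylase of base excision repair, fell from 15.2 to 7.30 CPM (log2 fold change -1.06), and MRM1, a mitochondrial rRNA methyltransferase, fell from 14.7 to 6.95 CPM (log2 fold change -1.08).

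In all, 165 genes were higher and 133 lower with the 20nt guide among 16358 tested, and 4046 had an unadjusted p under 0.05, where 818 were to be found by chance. Further rises were DDX39B (log2 fold change 3.02), the pseudogene RPS28P7 (2.61), the peptidase MME (0.86), SFN (0.81), the leptin receptor LEPR (0.78) and IZUMO3 (0.77). Further falls were the pseudogene BZW1P2 (-5.15), AMIGO3 (-1.34), the chaperone CANX (-0.96), PRR5 (-0.83), the readthrough PEDS1-UBE2V1 (-0.80) and the pseudogene LSM12P1 (-0.77). These counts were unstable. All A375 groups shared 1 estimate of spread, so the g[9nt] libraries enter this comparison too. The g[9nt] replicates differed most from each other, with a chi-square per gene between replicates of 18.9, against 6.54 in Safe Harbor and 5.22 in 20nt. Without any 1 Safe Harbor or 20nt library 1 to 2 genes were higher and 1 to 4 lower, without either g[9nt] library 1848 to 1865 were higher and 1776 to 1788 lower, and with length-scaled counts 1 was higher and 1 lower, CD81.

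By camera, 11 of 38 lists passed for the 20nt guide, and 0 passed with an estimated correlation (adjusted p = 0.648 with an estimated correlation for the matrix list and 0.734 for the others). Of 26 ATF4 targets, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with CHAC1, ASNS, SLC7A11 and ALDH1L2 (log2 fold change 0.71) among them (camera adjusted p = 0.00691). Of 26 cholesterol synthesis genes, 3 rose and 0 fell (7 and 0 adjusted over the list alone), namely SCD (0.45), STARD4 (0.61) and INSIG1 (0.34), at a camera adjusted p of 0.0175. Of 36 extracellular matrix genes, 3 rose and 0 fell (9 and 2 adjusted over the list alone), namely COL1A2, COL1A1 and ITGB3 (0.51), at a camera adjusted p of 0.000431. Of 29 markers of dedifferentiated melanoma, NT5E (0.34) and INHBA (0.36) rose and 0 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0199). Of 53 G2M phase genes, LBR (0.38) and CBX5 (0.37) rose and TUBB4B (-0.35) fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0459).

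Other lists were lower with the 20nt guide. Of 78 ribosomal protein genes, RPS27 rose (0.71) and RPS15 fell (-0.52), and 76 had a negative log2 fold change (1 higher and 29 lower adjusted over the list alone; median -0.25, camera adjusted p = 1.8e-09). Mean fragment lengths were 374 and 361 bases in the 20nt libraries and 323 and 316 bases in Safe Harbor, and with a trend with transcript length removed the median was -0.06 (camera adjusted p = 0.0457). Of 30 nucleolar and MYC-driven genes, 0 rose and 4 fell (0 and 8 adjusted over the list alone), namely PPAN (-0.37), NOP16 (-0.44), PES1 (-0.33) and NOP56 (-0.31), at a camera adjusted p of 0.000431. Replication histones (33 tested, median -0.31, camera adjusted p = 0.000574) and HOX genes (36 tested, median -0.11, camera adjusted p = 0.0175) had 0 members called by edgeR, before or when adjusted over the list alone. With the length trend removed, neither of these lists passed (camera adjusted p = 0.0571 and 0.0935). The chaperonin HSPE1 (-0.48) was the 1 member called of 19 heat shock genes and KRT10 (-0.41) the 1 of 16 epithelial markers, each also called adjusted over the list alone (camera adjusted p = 0.0199 and 0.0292). The epithelial list and the dedifferentiated melanoma list did not pass with the length trend removed either (camera adjusted p = 0.24 and 0.0619), while the nucleolar and heat shock lists did (medians -0.15 and -0.13, camera adjusted p = 8.9e-05 and 0.0139). Over 12 alternatives the 11 lists passed in 7 to 11.

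To determine what the truncated guide altered, g[9nt] libraries were compared with Safe Harbor. Many transcripts of secreted liver proteins were lower with g[9nt]. An action of the guide cannot be told apart here from RNA of a hepatocyte-type source in the Safe Harbor and 20nt libraries, as described further on. ALB, serum albumin, fell from 114 ± 21.4 CPM with Safe Harbor to 0.170 ± 0.0584 CPM (SD, n = 2 and 2, log2 fold change -9.37, SE 0.32, edgeR adjusted p = 3.9e-06). APOB, the main protein of low-density lipoprotein, fell from 75.5 to 0.249 CPM (log2 fold change -8.21), and ITIH2 and APOA2 changed by -7.76 and -7.94 on the log2 scale. F2, prothrombin, had 0 counts against 290 and FGB, a fibrinogen chain, 0 against 285, so they were at least 79.0-fold and at least 77.6-fold lower. APOA1 had 2 counts against 2176 (ratio 889, interval 246 to 7345), FGA 2 against 851 (ratio 348, interval 95.9 to 2875), and VIL1, villin, 1 against 401 (ratio 328, interval 58.5 to 12972). A hepatocyte list of 28 genes, written after these genes had been seen, summed to 617 and 561 CPM in the Safe Harbor libraries, 454 and 641 CPM with 20nt, and 56.6 and 61.2 CPM with g[9nt]. Its members TF and SERPINA1, chosen after their values were seen, fell less, from 89.5 to 33.1 CPM and from 69.9 to 18.5 CPM.

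The collagens COL1A1 and COL1A2 rose further than with the 20nt guide (by 0.99 and 0.96 on the log2 scale for g[9nt] against 20nt, edgeR adjusted p = 0.00733 and 0.00275), while COL5A2, chosen after its value was seen, stood at 269 CPM with Safe Harbor, 282 CPM with 20nt and 221 CPM with g[9nt]. COL1A1 went from 13.7 ± 1.63 to 47.0 ± 4.72 CPM (log2 fold change 1.78, SE 0.14, edgeR adjusted p = 0.000281) and COL1A2 from 6.11 ± 0.374 to 20.6 ± 1.16 CPM (log2 fold change 1.76, SE 0.11, edgeR adjusted p = 8.2e-05). The collagen cross-linker LOX rose by 1.32, the actin cross-linker FLNC by 1.46, and SNX25 by 1.32 on the log2 scale. NOTCH1 (2.90), RPS28P7 (2.82), DDX39B (2.39), MTRNR2L10 (1.82) and LDHAP7 (1.26) also rose. The g[9nt] libraries differed widely in NOTCH1 (30.0 ± 12.9 CPM) and DDX39B (10.3 ± 6.44 CPM, SD, n = 2). In all, 38 genes were higher and 133 lower among 16358 tested, with 1460 at an unadjusted p under 0.05. Of the 133 lower genes, 24 were on the hepatocyte list and 89 averaged under 1 CPM in g[9nt], while 44 averaged at least 1 CPM there. Leaving out g[9nt] replicate 2 gave 555 higher and 604 lower, leaving out either Safe Harbor library gave 19 higher, leaving out Safe Harbor replicate 2 gave 86 lower, and length-scaled counts gave 15 higher and 77 lower.

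Genes outside the liver type were among those 44, and the following were chosen after their values were seen. TOP3B, a topoisomerase, fell from 20.4 ± 0.337 to 3.71 ± 0.282 CPM (log2 fold change -2.46, SE 0.13, edgeR adjusted p = 2.2e-05). BMP8B, a secreted growth factor, fell from 25.6 ± 1.96 to 10.5 ± 0.590 CPM (log2 fold change -1.29, SE 0.09, edgeR adjusted p = 0.000165). SKA1, a kinetochore protein, fell from 9.37 ± 4.69 to 1.22 ± 0.185 CPM (log2 fold change -2.92, edgeR adjusted p = 0.00816). POLR3D, an RNA polymerase III subunit, fell from 85.1 to 50.6 CPM (log2 fold change -0.75), BTBD7 from 17.5 to 6.93 CPM (-1.34), and the tubulin TUBB3 from 453 to 271 CPM (-0.74). All 6 were also lower with g[9nt] than with 20nt (edgeR adjusted p from 0.000107 for TOP3B to 0.0331 for SKA1).

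**Figure D2:**
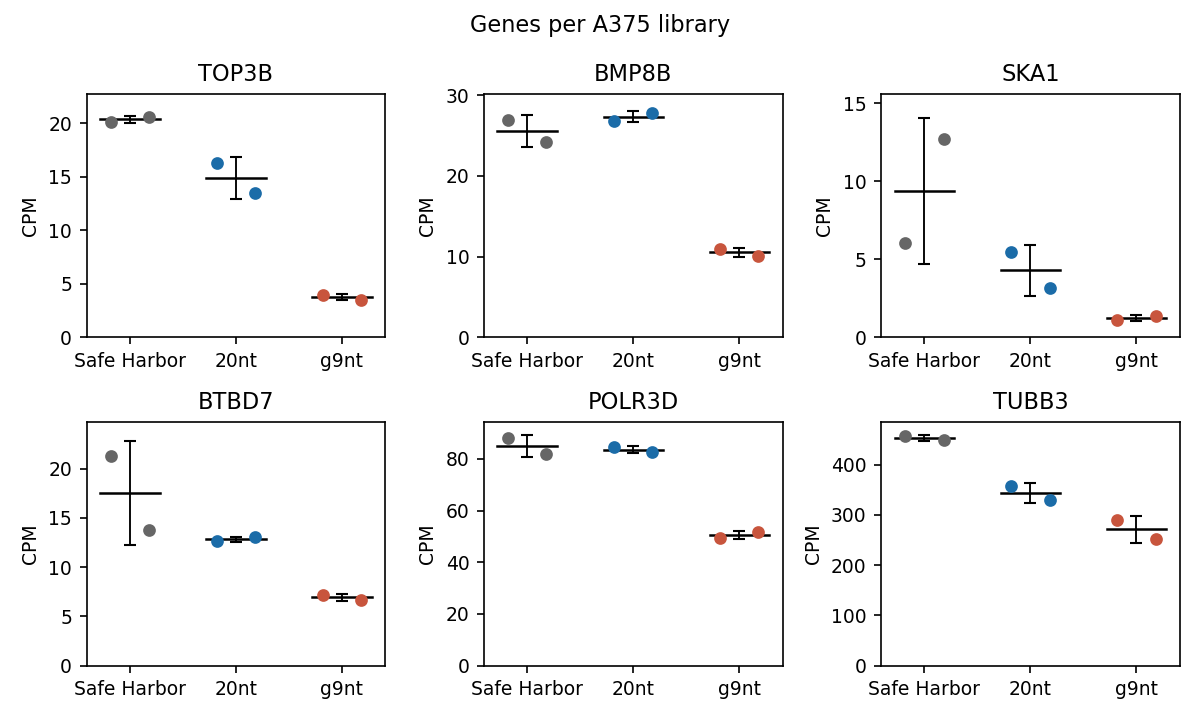
TOP3B, BMP8B, SKA1, BTBD7, POLR3D and TUBB3 in CPM in each A375 library, with the group mean as a bar and the SD as an error bar. TOP3B lies at 20.4 CPM on average with Safe Harbor, 14.9 CPM with 20nt and 3.71 CPM with g[9nt].

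By camera, 3 of 38 lists passed for g[9nt] against Safe Harbor and 0 with an estimated correlation (adjusted p = 0.8 with an estimated correlation for all 3). Of 78 ribosomal protein genes and 53 G2M phase genes, 0 were called by edgeR, before or when adjusted over the list alone, with median log2 fold changes of 0.11 and -0.08 (camera adjusted p = 4.6e-05 and 0.0448). With the length trend removed, the ribosomal median was 0.03 and its list did not pass (camera adjusted p = 0.0915), nor did the NK list (camera adjusted p = 0.0723), while the G2M list passed (camera adjusted p = 0.0283), as did replication histones (median -0.16, camera adjusted p = 0.0483), which had not before. Over 12 alternatives the ribosomal, G2M and NK lists passed in 8, 4 and 2. The ribosomal and G2M lists turned direction and did not pass without g[9nt] replicate 1 (camera adjusted p = 0.714 and 0.575). RPS27 stood at 0.57 and CDCA2, a mitotic gene, at -0.21. The NK marker list had 3 measured members, KLRD1 (0.72), NCAM1 (0.94) and NKG7 (-0.19), none called by edgeR over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.0474). The extracellular matrix list did not pass (camera adjusted p = 0.262), although 3 of its 36 members rose and 0 fell (4 and 2 adjusted over the list alone).

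To compare the guides with each other, g[9nt] was set against 20nt. SOX9, a transcription factor of neural crest and cartilage, rose from 10.6 ± 0.955 CPM with 20nt to 24.2 ± 2.0 CPM with g[9nt] (SD, n = 2 and 2, log2 fold change 1.19, SE 0.11, edgeR adjusted p = 0.000882). Some ATF4 targets were lower: SLC7A11 fell by 0.62, ASNS by 0.51, ALDH1L2 by 0.67 and CHAC1 by 1.15 on the log2 scale. ALB fell from 105 ± 22.9 to 0.170 CPM (log2 fold change -9.25, edgeR adjusted p = 4.5e-06), and APOB (-8.72), ITIH2 (-7.80), APOH (-7.36) and IGF2 (-7.56) fell alike. FGB and F2 had 0 counts with g[9nt] and were at least 62.1-fold and at least 56.3-fold lower. The counts of APOA1 (2 against 1273), FGA (2 against 764) and VIL1 (1 against 307) gave ratios of 500 (interval 138 to 4136), 300.3 (interval 82.8 to 2484) and 241 (interval 43 to 9563).

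In all, 901 genes were higher and 941 lower with g[9nt] than with 20nt, and 5151 had an unadjusted p under 0.05. At least 2-fold higher or lower were 40 and 158. Other rises included NOTCH1 (4.86), BZW1P2 (5.31), the cancer-testis antigen CTAG1B (1.84), AMIGO3 (1.53), MROH6 (1.15), the metallothionein MT1X (1.03), and the readthroughs PEDS1-UBE2V1 (1.12), ISY1-RAB43 (1.08) and FMC1-LUC7L2 (1.06). The g[9nt] libraries differed widely in CTAG1B (17.2 ± 13.6 CPM), NOTCH1 (30.0 ± 12.9 CPM) and MROH6 (9.85 ± 4.72 CPM, SD, n = 2). With length-scaled counts 46 genes were higher and 102 lower, without either 20nt library 14 to 19 were higher and 65 to 81 lower, without either Safe Harbor library 148 to 177 were higher and 189 to 192 lower, and without g[9nt] replicate 2 2606 were higher and 2708 lower.

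By camera, 5 lists passed between g[9nt] and 20nt, and 0 with an estimated correlation (adjusted p = 0.669 with an estimated correlation for all 5). Of 78 ribosomal protein genes, 35 rose and 0 fell (66 and 0 adjusted over the list alone), with RPL35 (0.76) and RPS28 (0.78) among them (median 0.36, camera adjusted p = 2.3e-15). Fragment lengths were 301 and 331 bases in g[9nt], and the median with the length trend removed was 0.08 (camera adjusted p = 0.00152). Of 53 G2M phase genes, 1 rose and 18 fell (5 and 29 adjusted over the list alone), among them CKAP2L (-0.49), HMMR (-0.36) and the topoisomerase TOP2A (-0.43), while TUBB4B rose (0.30), at a camera adjusted p of 0.00249. Of 26 ATF4 targets, 0 rose and 7 fell (0 and 7 adjusted over the list alone; camera adjusted p = 0.00568). HOX genes had 0 members called by edgeR (0 adjusted over the list alone; median 0.14, camera adjusted p = 0.0135), with HOXC11 at 0.39. Of 53 clustered protocadherins, PCDHGB1 rose (0.71) and PCDHGC5 fell (-2.60), 0 passed adjusted over the list alone, and the median was -0.18 (camera adjusted p = 0.045). With the length trend removed the HOX and protocadherin lists did not pass (camera adjusted p = 0.064 and 0.453), while the G2M and ATF4 lists did (camera adjusted p = 0.0002 and 0.00152), as did the nucleolar list and mitochondrial transcripts (medians 0.07 and -0.21, camera adjusted p = 0.0228 and 0.00563), which had not passed before. The 5 lists passed in 7 to 11 of the 12 alternatives.

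Both A375 guides were tested against the same Safe Harbor libraries, which ties their results together. COL1A1, COL1A2, SNX25, SFN, DDX39B and RPS28P7 were among 9 genes higher with both guides, and CD81, TUBB3 and FAM89B were among 5 genes lower with both. Independent lists of these sizes would share 0.383 and 1.08 genes, and the simulations of unchanged groups shared at most 2 in either direction. The log2 fold changes of both guides correlated across genes at r = 0.304, against 0.488 in the simulations, and their covariance was 0.0818 against 0.0328. The controls were too few to split, so part of the overlap can come from the shared control libraries. The other 2 genes lower with both, AGPAT1 and TRBC1, were chosen after their values were seen. AGPAT1 stood at -6.12 with g[9nt] and -1.90 with 20nt, and TRBC1 at -5.16 and -4.02. TRBC1, of the T cell receptor list, had 98 counts with Safe Harbor, 2 with g[9nt] and 6 with 20nt. The T cell lists, the check for contamination in A375, did not pass by camera.

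Jurkat libraries were of 2 depths, with Safe Harbor replicate 3 and sg4 replicates 1, 3 and 4 over 50 M estimated counts. The first principal component held 49.4% of the variance and separated these 4 libraries from the other 5. On it, sg4 replicate 1 scored 19.9, against 48.5 to 61.8 for the other libraries over 50 M and -57.5 to -21.5 for those under it. The second component held 16.1% and set sg8 apart from the other shallow libraries.

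**Figure D3:**
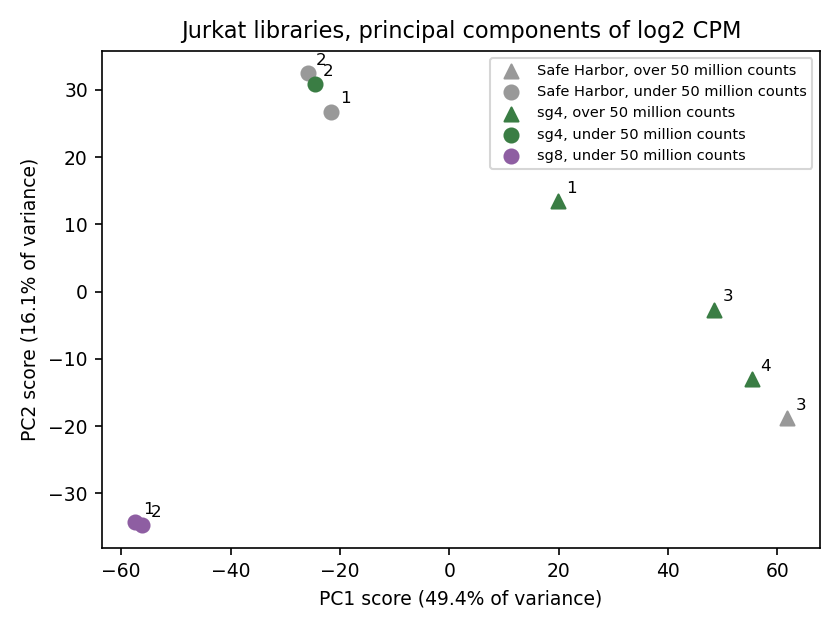
First and second principal component scores of the 9 Jurkat libraries, numbered by replicate. Triangles mark libraries over 50 M estimated counts and circles those under it. The first axis holds 49.4% of the variance and the second 16.1%.

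To determine the response to sg4 in Jurkat, its 4 libraries were compared with 3 Safe Harbor libraries. AC008878.3 (chromosome 19, 7382834 to 7472477), a gene model, fell from 30.9 ± 4.51 CPM (SD, n = 3) to 10.9 ± 1.29 CPM (SD, n = 4), the 1 gene called (edgeR log2 fold change -1.49, SE 0.13, adjusted p = 0.0176). The 4 genes with the next smallest p did not pass. AC119396.1, the neighbouring gene model (7348943 to 7383385), had 17.4 ± 0.525 CPM with Safe Harbor and 7.62 ± 1.27 CPM with sg4 (2.3-fold less, log2 SE 0.15, edgeR adjusted p = 0.132). AURKA, the mitotic kinase Aurora A, had 112 ± 2.10 and 74.9 ± 5.36 CPM (log2 fold change -0.58, SE 0.08, edgeR adjusted p = 0.132). PARN, a poly(A) ribonuclease, had 47.4 ± 2.42 and 69.5 ± 4.56 CPM (log2 fold change 0.55, edgeR adjusted p = 0.227), and CSRNP1 21.4 ± 1.22 and 11.2 ± 1.82 CPM (log2 fold change -0.92, edgeR adjusted p = 0.227).

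The surroundings of AC008878.3 were examined after its value was seen. With sg8, AC008878.3 and AC119396.1 stood at log2 fold changes of 0.14 and 0.06. Of 21 tested genes that start within 500 kb, 3 overlap AC008878.3 or are AC008878.3, and the other 18 had a median log2 fold change of -0.11, with 16 negative and 1 at an unadjusted p under 0.05, ENSG00000268400 (-2.01, edgeR adjusted p = 1). The insulin receptor INSR stood at -0.12, PNPLA6 at -0.13 and MCOLN1 at -0.22.

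Among 16108 genes, 0 were higher and 1 lower with sg4 by edgeR, with 225 at an unadjusted p under 0.05 where 805 were to be found by chance, and DESeq2 called 2 higher and 8 lower. With the replicate number as a block, 1 gene was higher and 5 lower, and 14 lists passed in place of 9. Within the shallow libraries, with 1 sg4 and 2 Safe Harbor libraries, 11 were higher and 15 lower, within the deep ones, with 3 and 1, 0 were higher and 0 lower, and the call of AC008878.3 was lost without Safe Harbor replicate 1 or 2, sg4 replicate 1, 2 or 4, or either sg8 library.

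By camera, 9 of 38 lists passed for sg4, and 0 with an estimated correlation; edgeR called 0 members in any of them over all genes. Of 23 MAPK output genes, 22 had a negative log2 fold change, among them the growth factor responders EGR1 (-0.83), SPRY4 (-0.81), EGR3 (-0.61) and ETV5 (-0.20), with 0 higher and 2 lower adjusted over the list alone (median -0.20, camera adjusted p = 6.9e-06, adjusted p = 0.082 with an estimated correlation). Of 26 T cell activation genes, 21 were negative, among them EGR1, IER2 (-0.24), FOSB (-0.52) and FOS (-0.72), with 0 higher and 1 lower adjusted over the list alone (median -0.21, camera adjusted p = 9.8e-05, adjusted p = 0.082 with an estimated correlation). Both lists passed with depth as a term (camera adjusted p = 0.0118 and 0.00526). Replication histones (median 0.25, with H3C11 at 1.67; camera adjusted p = 3.1e-05) and extracellular matrix genes (median 0.18, with POSTN at 1.44; camera adjusted p = 0.000798) were higher, each at an adjusted p = 0.439 with an estimated correlation and with 0 members passing adjusted over the list alone. Without sg4 replicate 2 the matrix list did not pass (camera adjusted p = 0.509), and COL1A1, chosen after its value was seen, stood at 131 CPM in that library and between 13.2 and 15.8 CPM in the other sg4 libraries. Ribosomal proteins had a median of 0.09 (camera adjusted p = 4.0e-05, adjusted p = 0.837 with an estimated correlation), and their direction turned with depth as a term.

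Of the remaining sg4 lists, G2M phase genes had a median of 0.07 with AURKA as the 1 member lower adjusted over the list alone (camera adjusted p = 0.00454, adjusted p = 0.482 with an estimated correlation). S phase genes had a median of 0.06, with UHRF1 at -0.67 (camera adjusted p = 0.00804, adjusted p = 0.439 with an estimated correlation). Clustered protocadherins, whose promoters bind CTCF, had 17 of 20 members negative, with PCDHB14 at -0.64 (median -0.40, camera adjusted p = 0.0121, adjusted p = 0.397 with an estimated correlation), and did not pass without Safe Harbor replicate 1 or 2, sg4 replicate 2 or either sg8 library (camera adjusted p from 0.15 to 0.68). Mitochondrial transcripts had 12 of 13 negative, with MT-ND1 at -0.25 (camera adjusted p = 0.0121, adjusted p = 0.822 with an estimated correlation). Their share of counts was lowest in sg4 replicate 3, at 1.58%. It was 2.24% to 2.80% in the other sg4 libraries and 2.30% to 2.86% in Safe Harbor. The list kept its direction in all 15 alternatives and passed in 10. In S phase, protocadherin and mitochondrial lists 0 members passed adjusted over the list alone. Over 15 alternatives the 9 lists passed in 8 to 14.

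To determine the response to sg8 in Jurkat, its 2 libraries were compared with the same 3 Safe Harbor libraries. Extracellular matrix and skin-type transcripts were higher: COL5A2, a fibrillar collagen, rose from 1.38 ± 0.198 CPM (SD, n = 3) to 11.8 ± 2.28 CPM (SD, n = 2), an 8.55-fold rise (edgeR log2 fold change 3.10, SE 0.28, adjusted p = 0.00907). The elastic fibre protein ELN rose by 3.42, the matrix protease MMP2 by 3.04, and the desmosome protein DSP by 3.57 on the log2 scale, and COL6A3 rose 5.66-fold. A list of 28 skin genes was written after these genes had been seen. It summed to 1571 and 1292 CPM in the sg8 libraries, against 57.0 to 287 CPM in the other Jurkat libraries and 379 to 454 CPM in A375. Without its matrix genes it summed to 227 and 216 CPM in sg8, 28.9 to 54.6 CPM in the other Jurkat libraries and 353 to 384 CPM in A375. Of its 27 tested members, 3 were called higher by edgeR and 0 lower, and 26 had a positive log2 fold change. PARN rose from 47.4 ± 2.42 to 86.9 ± 2.46 CPM (log2 fold change 0.87, SE 0.09, edgeR adjusted p = 0.00907). TBCE, a tubulin folding cofactor, fell from 43.4 ± 0.810 to 22.9 ± 2.89 CPM (log2 fold change -0.92, SE 0.10, edgeR adjusted p = 0.00907), and IGF2BP3, an RNA-binding protein of fetal tissues, fell from 65.2 ± 5.66 to 38.5 ± 0.709 CPM (log2 fold change -0.76, SE 0.11, edgeR adjusted p = 0.024).

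**Figure D4:**
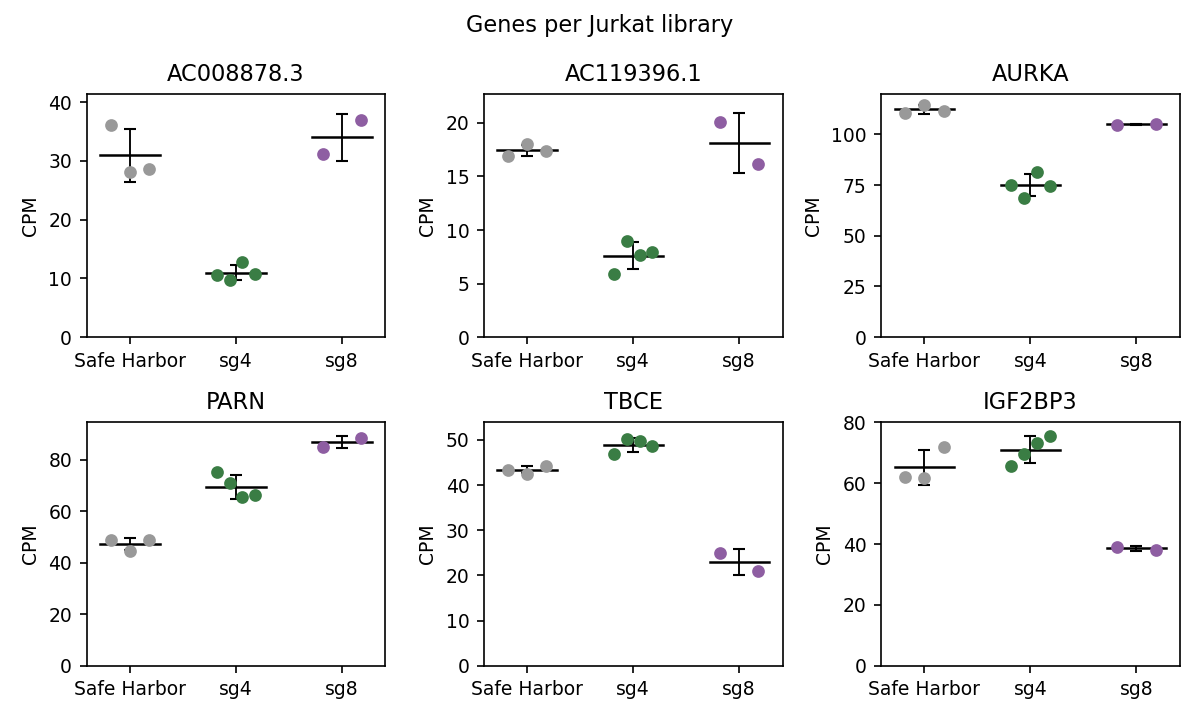
AC008878.3, AC119396.1, AURKA, PARN, TBCE and IGF2BP3 in CPM in each Jurkat library, with the group mean as a bar and the SD as an error bar. TBCE lies between 20.9 and 25 CPM in the sg8 libraries and between 42.6 and 50.1 CPM in the other Jurkat libraries.

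In all, 46 genes were higher and 3 lower with sg8 among 16108, with 724 at an unadjusted p under 0.05 where 805 were to be found by chance. Further rises were FBLN1 (1.29), the nuclear lamin LMNA (1.28), COL6A2 (1.25) and the actin-severing GSN (2.29-fold). The third lower gene, ZNF625-ZNF20, a readthrough at 1.75 CPM with Safe Harbor and 0 with sg8, was chosen after its value was seen. With a minimum of 1 CPM in every group 8 were higher, with depth as a term 148 were higher and 6 lower, and within the shallow libraries, 2 of each group, 265 were higher and 37 lower. With only these 2 groups in the fit, or without Safe Harbor replicate 1 or 2 or either sg8 library, 0 were higher and 0 lower, and without any 1 of sg4 replicates 1, 3 and 4, 24 to 26 were higher.

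By camera, 9 lists passed for sg8, and the matrix and dedifferentiated melanoma lists also passed with an estimated correlation. The melanocyte and dedifferentiated melanoma lists, set beforehand as a check for contamination in Jurkat, were both among the 9. For the lists that rose, an action of sg8 cannot be told apart here from reads of another source. Of 35 extracellular matrix genes, 6 rose and 0 fell (20 and 0 adjusted over the list alone), with POSTN (3.57) beside COL5A2, COL6A3 and MMP2 (median 1.53, camera adjusted p = 5.2e-28, adjusted p = 0.0259 with an estimated correlation). Of 27 dedifferentiated melanoma markers, the caveolin CAV1 rose (4.13) and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.0247 with an estimated correlation). Of 14 CD81 partners, the claudin CLDN1 (77 counts against 3, ratio 70.9, interval 23.4 to 352) and CD44 (2.48) rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.00345, adjusted p = 0.0927 with an estimated correlation). Epithelial markers had 0 members called by edgeR, with 6 higher and 2 lower adjusted over the list alone, KRT14 at 4.90 and KRT10 at 1.46 (camera adjusted p = 8.3e-06, adjusted p = 0.0648 with an estimated correlation). Melanocyte genes had 0 called and 2 higher adjusted over the list alone, SLC24A5 at 20 counts against 1 (ratio 55.3, interval 8.84 to 2291) and PMEL at 1.40 (camera adjusted p = 0.0119, adjusted p = 0.251 with an estimated correlation).

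The other 4 lists had 0 members called, before or when adjusted over the list alone, and each had an adjusted p = 0.787 with an estimated correlation. Ribosomal proteins had a median of -0.16, with RPL29 at -0.31 (camera adjusted p = 8.6e-07). All 30 nucleolar and MYC-driven genes had a positive log2 fold change, with WDR12 at 0.13 (median 0.24, camera adjusted p = 0.00449). Interferon-stimulated genes had a median of -0.13, with IRF9 at -0.84 (camera adjusted p = 0.00467). Neural markers had a median of 0.74, with MAP2 at 1.02 (camera adjusted p = 0.0118). The 9 lists of sg8 passed in 9 to 15 of 15 alternatives.

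**Figure D5:**
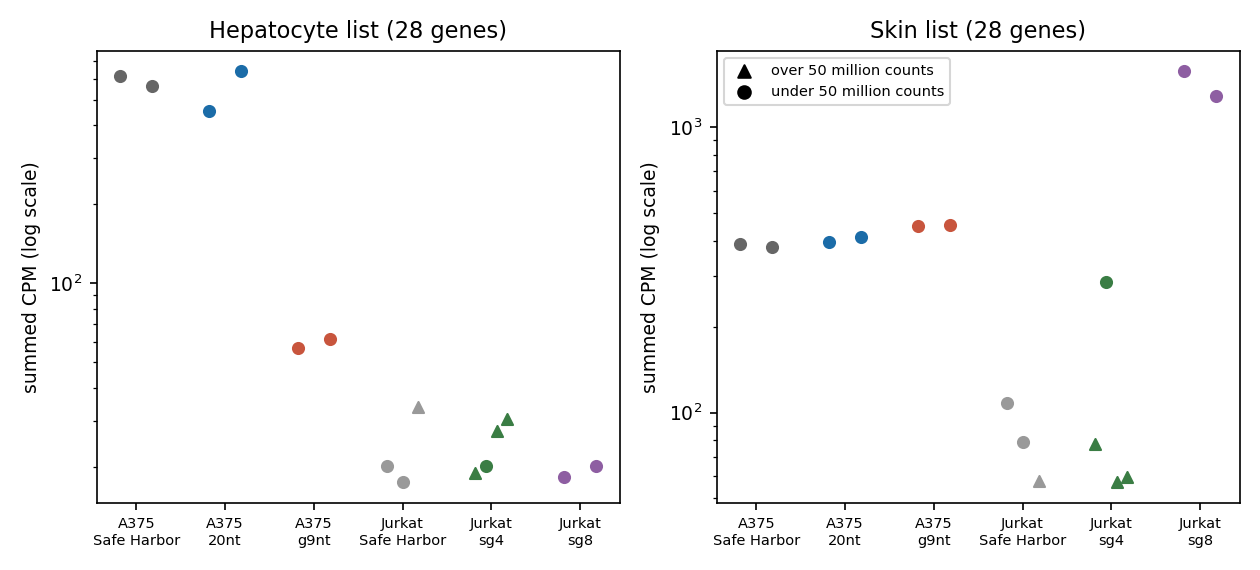
Summed CPM, on a log axis, of the hepatocyte list (left) and the skin list (right) in each of the 15 libraries. Triangles mark libraries over 50 M estimated counts. The skin list sums to 1571 and 1292 CPM in the Jurkat sg8 libraries, or to 227 and 216 CPM without its matrix genes (not drawn). The hepatocyte list sums to 56.6 and 61.2 CPM in A375 g[9nt].

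To compare both Jurkat guides, sg4 was set against sg8. TBCE was higher with sg4, at 48.9 ± 1.49 CPM (SD, n = 4) against 22.9 ± 2.89 CPM (SD, n = 2) with sg8 (edgeR log2 fold change 1.09, SE 0.10, adjusted p = 0.00419), and IGF2BP3 was higher by 0.88 (SE 0.10, edgeR adjusted p = 0.00658). The spindle orientation protein GPSM2 (0.55), MNS1 (1.05), KIAA1191 (0.48) and CD1B, a lipid antigen-presenting molecule of T cell precursors (0.47), were also higher. AURKA was lower with sg4 (log2 fold change -0.48, SE 0.08, edgeR adjusted p = 0.0349). The keratins KRT5 (-7.54) and KRT10 (-1.69), DSP (-4.96), ELN (-3.39), the pseudogene RPLP0P12 (-3.17), MMP2 (-2.65), COL5A2 (-2.59), COL6A3 (-2.35), SPARC (-1.86) and COL5A1 (-1.69) were lower with sg4. The skin list sums in sg8 were 1571 and 1292 CPM, or 227 and 216 CPM without its matrix genes.

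In all, 8 genes were higher and 154 lower with sg4 than with sg8, with 1385 at an unadjusted p under 0.05. With a minimum of 1 CPM in every group 17 were lower, with depth as a term 65, and with the replicate block 89. Without either sg8 library 0 were higher and 0 lower, without any 1 of sg4 replicates 1, 3 and 4, 33 to 48 were lower, and without Safe Harbor replicate 3 12 were higher and 243 lower.

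By camera, 16 lists passed between sg4 and sg8, and 0 with an estimated correlation. The melanocyte and dedifferentiated melanoma lists, the check for contamination in Jurkat, were among the 16. Of 35 matrix genes, 0 rose and 9 fell (0 and 22 adjusted over the list alone; median -1.49, camera adjusted p = 1.8e-15, adjusted p = 0.0745 with an estimated correlation). Of 14 epithelial markers, KRT14 (1 count against 245, ratio 1299, interval 231 to 51531), KRT5, KRT10 and KRT19 (-6.18) fell and 0 rose (2 higher and 7 lower adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.0745 with an estimated correlation). CLDN1 (2 counts against 77, ratio 204, interval 54.6 to 1716), CD44 (-2.23) and PTGFRN (-1.36) fell among 14 CD81 partners, with 0 and 4 adjusted over the list alone (camera adjusted p = 0.00407, adjusted p = 0.125 with an estimated correlation). CAV1 (-3.03) and PDGFRB (-1.79) fell among 27 dedifferentiated melanoma markers, with 0 and 5 adjusted over the list alone (camera adjusted p = 0.000161, adjusted p = 0.0745 with an estimated correlation). The endothelial VWF (-3.00; 0 and 3 adjusted over the list alone) and the melanocyte transporter SLC24A5 (2 counts against 20, ratio 53, interval 12.9 to 468; 0 and 2 adjusted over the list alone) each fell in lists that passed (camera adjusted p = 0.0166 and 0.0263, adjusted p = 0.189 and 0.295 with an estimated correlation).

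The other 10 lists held at most 1 called member. G2M phase genes had a median of 0.16, with AURKA lower and 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 0.000963, adjusted p = 0.435 with an estimated correlation). Neural markers had a median of -1.27 with 0 called and 1 lower adjusted over the list alone, DCX at -4.38 (camera adjusted p = 0.000963, adjusted p = 0.53 with an estimated correlation). In the remaining 8 lists 0 members passed, before or when adjusted over the list alone. Ribosomal proteins (median 0.25, camera adjusted p = 6.3e-11), replication histones (0.39, 0.000189), interferon-stimulated genes (0.17, 0.000762) and cholesterol synthesis genes (0.13, 0.0465) were higher as lists. Nucleolar genes (median -0.32, camera adjusted p = 0.00233), MAPK output (-0.26, 0.00428), mitochondrial transcripts (-0.25, 0.0238) and clustered protocadherins (-0.39, 0.0465) were lower as lists, and the nucleolar list turned with depth as a term and with the replicate block. Over 15 alternatives the protocadherin, cholesterol and mitochondrial lists passed in 5, 6 and 7, and the other 13 lists in 10 to 14. Their 8 values ran from adjusted p = 0.189 with an estimated correlation for MAPK output to 0.73 for the nucleolar list.

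Log2 fold changes of sg4 and sg8 against Safe Harbor correlated across genes at r = -0.109, where simulated unchanged groups gave 0.447, and at 0.203 with depth as a term. Their covariance was -0.0341 against 0.0738 in the simulations. No gene was called with both guides by edgeR in the same direction. With 1 gene called for sg4, independent lists would share 0 higher and 0.00019 lower genes, so this count cannot tell whether the guides act alike. Genes are not independent replicates, and the correlation and covariance share the Safe Harbor libraries.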

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

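The tests on the hepatocyte and skin lists and the removal of a trend with transcript length were chosen only after the results they address were seen.

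In groups of 4 libraries, 35 values were examined for a library that lies far from the rest, where chance gives about 1.8. In sg4, 2 values stood out, both in replicate 2, the 1 shallow sg4 library. ELN stood at 1.43 CPM there and between 0.501 and 0.602 CPM in the others. The skin list summed to 287 CPM there and to between 57.0 and 77.4 CPM in the others. Most of this excess lay in its matrix genes. COL1A1, COL1A2 and COL3A1, all chosen after their values were seen, stood at 130.8, 59.7 and 43.5 CPM there. In the others they reached at most 15.78, 9.73 and 6.79 CPM. Without its matrix genes the list summed to 45.5 CPM there and to between 28.9 and 44.96 CPM in the others, so it hardly stood out. Among its keratins, KRT25 and KRT71 stood at 3.10 and 2.69 CPM there and at no more than 0.0131 CPM in the others. KRT10 and KRT1 (21.9 and 9.13 CPM there) lay within the others. These 4 were chosen after their values were seen. KRT25 and KRT71 were not particular to that library. In the shallow Safe Harbor replicates 1 and 2, KRT25 stood at 3.12 and 1.76 CPM and KRT71 at 3.18 and 1.51 CPM. In the deep Safe Harbor replicate 3 both stood at 0 CPM.

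Liver-type transcripts were lower in A375 g[9nt] than in Safe Harbor and 20nt, with ALB (114 CPM) and APOB (75.5 CPM) abundant in Safe Harbor. All 18 tested members of a hepatocyte list whose values had been seen when the list was written were lower in g[9nt], and so were 6 of the 9 others, so RNA from a hepatocyte-type source in the Safe Harbor and 20nt libraries is a candidate explanation. In g[9nt], 4 of the 28 listed genes averaged at least 1 CPM (TF 33.1 CPM, SERPINA1 18.5 CPM), and between the 20nt replicates 18 members moved together by a ratio of 1.46 (SD of log2 0.172), but less closely between the Safe Harbor replicates (ratio 1.17, SD of log2 0.584). An action of the g[9nt] guide cannot be told apart from this, since no other group carries it: the list's median log2 fold change was -6.08, or -5.33 with genes at 0 counts set to their bound, against -2.26 for CD81. TOP3B, BMP8B and POLR3D, which keep at least 1 CPM in g[9nt], are not on the list and stay outside either test.

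Extracellular matrix and skin-type transcripts were higher in Jurkat sg8 than in Safe Harbor, with 26 of 27 skin list members positive but 3 called, and KRT1 (10.7 and 10.0 CPM) and KRT2 (1.25 and 1.36 CPM) about level. Skin list members whose values had not been seen when the list was written rose as well (median log2 fold change 3.15, 6 of 7 positive, 0 called, camera p = 0.00319 with an estimated correlation, and from 0.00162 to 0.00917 without 1 library), so reads from skin-type tissue are a candidate explanation. An action of the sg8 guide alone does not predict a difference among libraries without it. Yet among these the skin list was higher in the shallow than in the deep ones (median log2 fold change 1.85, and from 1.10 to 2.20 without 1 library). The camera p with an estimated correlation was 0.0256, but between 0.057 and 0.0811 without Safe Harbor replicate 3, sg4 replicate 1 or sg4 replicate 2. Without matrix genes that p was 0.0604, and for members not seen before it was 0.267 (median 0.25, 4 of 7 positive), and reads carried over from sg8 libraries would raise the list as well, so the guide cannot be told apart from a skin-type source. TBCE, IGF2BP3 and PARN are not on the skin list, and no technical explanation was tested for them.

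Short transcripts, ribosomal proteins among them, were lower in A375 20nt. Across 16358 genes the log2 fold change rose with transcript length (Spearman rho 0.304 across genes, which are not independent replicates), from a median of -0.12 among the shortest transcripts (up to 1109 bases) to 0.11 among the longest (from 3086 bases). With that trend removed, the median of the ribosomal protein list moved from -0.25 (SD 0.18) to -0.059 (SD 0.16), and its camera adjusted p from 1.8e-09 to 0.0457, so fragment length is a candidate explanation for most of the shift. The list's median also lay at percentile 1.71 of 10000 random lists matched on length and expression, whose median was -0.20, so a small effect of the 20nt guide on these genes stays open too. Matched genes were few, with a pool of 168 distinct genes, which weakens that test.

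For sg4 against Safe Harbor, 3 of the 35 splits of the 7 libraries called at least as many genes as the real split, which called 1, so chance cannot be excluded. The highest other split called 7735 and set Safe Harbor replicate 3 and sg4 replicates 3 and 4 against replicates 1 and 2 of both groups. A split by depth, which differs only in the side of sg4 replicate 1, called 3138. This points to a structure of these samples other than the guide. The depth classes do not fully describe it, so a term for depth may not remove all of it. Of the 8 splits that part 3 numbered pairs, as the real one does, the real one called the most, and the highest other called 0. Pairs by number are not established, so this subset does not exclude chance either. With the replicate number as a block, the real split called 1 gene higher and 5 lower.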

How the results depend on the processing

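The depth term, the shallow or deep libraries alone, the minimum of 1 CPM in every group and the removal of the length trend were chosen after seeing the data; the other alternatives were not. CD81 fell with both A375 guides under every alternative run, with log2 fold changes from -3.02 to -2.89 for 20nt and from -2.54 to -2.01 for g[9nt] when 1 library was left out. Counts of changed genes moved with most alternatives. Where a group is left with 1 library, that library is assumed to vary like the others of its line. Unless stated, the cause of a shift was not tested. Depth limits genes of low level: a group at 0 counts gives only a bound.

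For 20nt against Safe Harbor (165 higher, 133 lower, 11 lists), DESeq2 called 570 and 641, no filter 1120 and 1128, length-scaled counts 1 and 1 with 7 lists, only the 2 groups compared 1869 and 1800, and at least 2-fold 7 and 13. Removing the length trend gave 510 and 665 with 7 lists, and an estimated correlation 0 lists. Leaving out 1 library gave 1 to 1865 higher, 1 to 1788 lower and 7 to 12 lists.

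For g[9nt] against Safe Harbor (38 higher, 133 lower, 3 lists), no filter called 189 and 326, length-scaled counts 15 and 77 with 1 list, and a minimum of 1 CPM 44 lower. Only the 2 groups compared gave 1 list and an estimated correlation 0. Leaving out 1 library gave 19 to 555 higher, 86 to 604 lower and 0 to 6 lists, with the most genes without g[9nt] replicate 2 and 0 lists without Safe Harbor replicate 1.

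For g[9nt] against 20nt (901 higher, 941 lower, 5 lists), no filter called 1674 and 1969, length-scaled counts 46 and 102, only the 2 groups compared 179 and 194, and at least 2-fold 40 and 158. An estimated correlation left 0 lists. The CD81 log2 fold change was 0.60 with length-scaled counts and 0.70 with only the 2 groups, and neither passed (adjusted p = 0.139 and 0.0626). Leaving out 1 library gave 14 to 2606 higher, 65 to 2708 lower, 3 to 7 lists, and a CD81 log2 fold change from 0.41 to 0.94 with an adjusted p from 4.3e-05 to 0.247. The correlation of A375 fold changes ranged from 0.22 to 0.51 when 1 library was left out.

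For sg4 against Safe Harbor (0 higher, 1 lower, 9 lists; 225 genes at an unadjusted p under 0.05), DESeq2 called 2 and 8, only the 2 groups compared 0 lower, the shallow libraries 11 and 15, and the deep ones 0 lower. An estimated correlation left 0 lists. Leaving out 1 library gave 0 to 1 higher, 0 to 5 lower and 7 to 12 lists, with the 1 higher and 5 lower without Safe Harbor replicate 3.

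For sg8 against Safe Harbor (46 higher, 3 lower, 9 lists), DESeq2 called 156 and 18, no filter 72 higher, only the 2 groups compared 0 and 0, at least 2-fold 1 lower, a minimum of 1 CPM 8 higher, the depth term 148 and 6 with 6 lists, and the shallow libraries 265 and 37. An estimated correlation left 2 lists. Leaving out 1 library gave 0 to 63 higher, 0 to 3 lower and 5 to 10 lists, with 5 lists without Safe Harbor replicate 3 or sg8 replicate 1.

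For sg4 against sg8 (8 higher, 154 lower, 16 lists), DESeq2 called 27 and 275, at least 2-fold 4 higher, a minimum of 1 CPM 17 lower, the depth term 65 lower, and the shallow libraries 27 higher. An estimated correlation left 0 lists. Leaving out 1 library gave 0 to 12 higher, 0 to 243 lower and 11 to 17 lists. The correlation of Jurkat fold changes turned from -0.109 to 0.203 with the depth term, and ranged from -0.243 without sg4 replicate 2 to 0.185 without Safe Harbor replicate 1.

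With a replicate block, 20nt against Safe Harbor gave 256 higher and 258 lower, sg4 against Safe Harbor 1 higher, 5 lower and 14 lists, sg8 against Safe Harbor 7 lower, and sg4 against sg8 89 lower. Same-numbered libraries correlated by 0.018 to 0.072 in A375 and by 0.038 and 0.0082 for sg8 against Safe Harbor, so there they share only a number. For sg4 against Safe Harbor the correlations were higher. The highest, 0.643, joined libraries of different number, so pairs by number are not established there either. The block left the other counts within 1.5 times.

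Of the other genes named and called, 0 of 39 for 20nt against Safe Harbor, 13 of 20 for g[9nt] against Safe Harbor and 12 of 36 for g[9nt] against 20nt were called under every alternative run. In Jurkat, 0 of 1 for sg4, 0 of 16 for sg8 and 0 of 26 for sg4 against sg8 were.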

Other observations

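Genes and tests in this part were chosen only after the results were seen, apart from the gene lists.

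Several A375 genes outside the hepatocyte list were lower with g[9nt] than with both Safe Harbor and 20nt while keeping at least 1 CPM. COMMD7 went from 27.4 CPM with Safe Harbor to 14.4 CPM with g[9nt] (log2 fold change -0.93, edgeR adjusted p = 0.00188), and PLEKHA3 from 23.2 to 12.1 CPM (-0.93, edgeR adjusted p = 0.00209). MOAP1, a modulator of apoptosis, went from 22.2 to 10.8 CPM (-1.04), RANGRF from 23.6 to 15 CPM (-0.66) and RBMS2 from 42.7 to 29.1 CPM (-0.56). The ciliary genes KIF27 and TMEM67 went from 4.63 to 1.27 CPM (-1.86) and from 12 to 6.30 CPM (-0.93). Of the 44 genes lower than Safe Harbor that keep at least 1 CPM, 35 were also lower than 20nt. The 44 include 3 genes of the hepatocyte list, TF, SERPINA1 and ASGR1, and others known from liver or hepatoma, such as PEG10 (46.6 to 3.56 CPM), A2M (27.4 to 1.35 CPM), APOE (20.5 to 1.01 CPM), GPC3 and SELENOP, which were not counted.

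Processed and other pseudogenes made up 18 of the 38 genes higher with g[9nt] than with Safe Harbor, 47.4% against 7.59% of tested genes (Fisher's exact test, odds ratio 11.1, Benjamini-Hochberg adjusted p = 2.7e-10), and 0 of the 133 lower ones (adjusted p = 0.000102). They also made up 34 of the 154 genes lower with sg4 than with sg8, or 22.1% (odds ratio 3.57, adjusted p = 3.0e-08), but 4 of the 46 higher with sg8 than with Safe Harbor (adjusted p = 1). They were rarer than among tested genes in the 901 genes higher (30, adjusted p = 1.7e-07) and the 941 lower (15, adjusted p = 4.7e-16) with g[9nt] than with 20nt, and in the 165 higher with 20nt than with Safe Harbor (4, adjusted p = 0.0134). Pseudogenes share reads with their parent genes, so these values are uncertain. Genes are not independent replicates, and these p-values do not measure the spread between libraries.

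Of the 38 tested lists, 16 passed in none of the 6 comparisons. Their smallest camera adjusted p was 0.0631 for myeloid markers, 0.0684 for CTCF and cohesin, 0.0701 for the CD81 region, 0.11 for imprinted genes, and 0.138 for both the unfolded protein response and T cell receptor signalling. It was 0.171 for B cell markers, 0.179 for NF-kB targets, 0.203 for erythroid markers, 0.205 for the heterochromatin and KRAB pathway, 0.214 for MHC genes and 0.215 for p53 targets. It was 0.261 for hypoxia and glycolysis, 0.338 for T-ALL regulators, 0.4 for tetraspanins and 0.486 for apoptosis.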
